A study of Mus musculus with 36 samples.

How the data were processed

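RNA of mouse embryonic stem cells was profiled by bulk 3' RNA sequencing in 36 libraries, 3 for each of 12 culture conditions. Per the labels, the line was a FUCCI embryonic stem cell line of 129/sv origin, cells grew for about 18 h to about 24% confluence before a treatment of 72 h, the medium held 15% serum and, unless stated, LIF at 1000 U/mL, and libraries were made from Trizol-extracted RNA with a Lexogen QuantSeq 3' kit. Groups and replicate numbers were taken from the sample labels.

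The 11 deposited tables, 1 for each condition compared with NS, hold read counts per gene for 21516 genes, and the same 3 NS columns stand in every table. Per the submitters' processing notes, the tools named for the work were CASAVA 1.8.2, STAR, HTSeq and edgeR and the genome build was mm9; the roles, settings, annotation and strand used in counting are not given in the sources used here. The counts are the authors' raw counts per gene, with no normalization. Per the file headers, the deposited tables also give the authors' own log2 fold change, log2 CPM (logCPM), likelihood ratio, p-value and FDR, fold and group averages with standard deviations. Of these only the authors' count of genes at a deposited FDR under 0.05 is printed, as that of the authors' table. No genome of the mm9 build was used, so no coordinates are given; a GRCm38 annotation served for gene names, length, GC content and host genes. Gene symbols are those of the tables, some of them older names (Tcfcp2l1, Tcfap2c, Dub1, Usp17l5, Sc4mol, Pkm2). Genes of multi-copy families (Zscan4, Usp17 and Dub1, Rpl10l and Rpl39l against their parent genes, histones), small nucleolar RNA genes inside host genes and antisense genes are uncertain, since their reads can be split or shared in counting.

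Library totals ran from 1848254 to 7288084 counts (median 4822563), and 18157 genes had a count in at least 1 library. Genes were kept by edgeR's filterByExpr with the group as design, which left 13498. Libraries were scaled by TMM, and CPM, the counts scaled to a common library size, use the TMM-scaled totals. One model with a mean for each of the 12 groups was fitted to the 36 libraries (estimateDisp and glmQLFit with robust estimation, 24 residual degrees of freedom, common biological coefficient of variation 0.31). Each of 16 comparisons of 2 groups was tested with edgeR's quasi-likelihood test, and the 4 higher doses of the toxicants with its F test. All adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. Log2 fold changes are those of the fit, and their SE is the log2 fold change divided by the square root of the F statistic. Log2 CPM used a prior count of 2, and errors of levels are SD over 3 libraries. Against a group with no count, a fold is a lower bound computed from 3 counts over the group; with 1 to 3 counts, a ratio has its exact 95% counting interval. Molecular identifiers are not named in the sources used here, so intervals and floors cover counting error only. Between replicates of a group, chi-square per degree of freedom over genes was 5.15 to 64.41, more than counting error alone would give. No library was thus a second sequencing of another of its group, but a second preparation of the same RNA is not excluded.

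The tests, the 29 gene lists, the alternatives and the rule for named genes were fixed before the data were examined, except where the text says otherwise. The rule named, for each comparison with NS, the 6 largest rises and 6 largest falls among genes with adjusted p under 0.05, no overlap between the libraries of the groups, a mean of at least 10 CPM in the higher group and a symbol that is not a predicted-gene name, and 4 of each for the other comparisons of 2 groups. From each list described it named up to 3 members with the smallest adjusted p past the threshold and, for a list tied to the treatment, up to 3 further members whatever their p. A list was described when it passed or was tied to the treatment. The values of 1 gene that the rule named are not reported here. The rule left no gene to name for the test of the 4 higher doses, for which it asked for the 6 smallest p by the same filters. Lists were tested with camera (limma) at a preset correlation of 0.01 between genes and adjusted over the 29 lists of a comparison, and again with the correlation estimated from the data. Counts of list members are given over all genes tested and adjusted over the list alone.

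Replicate numbers were checked for pairing by the correlation of libraries' deviations from their group means. It averaged 0.17 between libraries of the same number and different groups and -0.08 between different numbers. The second value largely follows from the first, because deviations from a group mean cancel out within the group. In 10 of the 16 comparisons every same-number pair exceeded 0.1 (ND, BP1, BP4, Cort10, DEP5, DEP10 and PFOA60 against NS, BP4 against BP1, DEP10 against DEP5 and PFOA100 against PFOA60), and the numbers were taken as pairing there. The pairing comes from the data; the labels do not say what a number marks.

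Alternatives were RLE size factors, DESeq2, no filter on low counts, a filter at a mean of 10 CPM, a fit of the compared groups only, the replicate number as a block, leaving out each replicate in turn, and for lists an estimated correlation, fry and the block. After the data were seen, the edgeR likelihood ratio test, a fit without the replicate-3 libraries of every group, list and signature tests with each library left out, and a fit without NS libraries 2 and 3 were added. In the last fit, the lone NS library is assumed to vary like the other groups. The test was run on simulated counts of all groups, with the real library sizes, each gene's mean over all libraries and its fitted spread. In BP4, 200 genes were changed among 13057, in sets of 50 per fold size, drawn only from genes above a minimum mean CPM. Shares recovered in BP4 against NS are given with the BP results. There, 3 unchanged genes were called (11 by DESeq2). In a simulated comparison with no change, 0 genes were called. Shared controls were simulated 20 times, with every library, NS included, drawn anew around the NS mean. Work was done in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and in Python 3.11.15 with matplotlib 3.10.9.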

Results

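Gene expression was measured in mouse embryonic stem cells of a FUCCI line, which carries fluorescent reporters of the cell cycle phase, after 72 h in 12 culture conditions. Each condition had 3 libraries, which the labels describe as separate biological experiments, so that every mean ± SD is over n = 3. The reference condition, NS, kept leukemia inhibitory factor (LIF), a cytokine that holds mouse embryonic stem cells in self-renewal. LIF was left out in ND, the condition labelled as normal differentiation, and in RA, which received 1 µM retinoic acid. The other conditions kept LIF and received 300 mM sorbitol (Sorb300), BP at 1 or 4 µM (BP1, BP4), cortisol at 10 or 60 µM (Cort10, Cort60), DEP at 5 or 10 µM (DEP5, DEP10) or PFOA at 60 or 100 µM (PFOA60, PFOA100). BP and DEP are given as the labels write them. Per the labels, the lower dose of each toxicant was the lowest with an observed effect on growth and the higher dose suppressed growth by 75%.

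Library totals ran from 1848254 to 7288084 counts with a median of 4822563. The NS libraries held 3029979 to 4624049 counts, the ND libraries 4799398 to 6811150, the RA libraries 2577459 to 5524311 and the Sorb300 libraries 2267565 to 5097071. The BP libraries held 4094709 to 6377296 counts (BP1) and 1848254 to 5498463 (BP4), and the cortisol libraries 2619119 to 7288084 (Cort10) and 2249286 to 5862896 (Cort60). The DEP libraries held 2297407 to 5358777 counts (DEP5) and 2689512 to 3800420 (DEP10), and the PFOA libraries 2515812 to 6533360 (PFOA60) and 2204617 to 6365654 (PFOA100). A gene with 3 counts stood at 0.41 to 1.62 CPM (counts scaled to the size of the library), depending on the library. This range uses raw library totals, whereas the other CPM values use TMM-scaled totals. The first principal component of log2 CPM held 23.6% of the variance and the second 17.4%. Ribosomal protein genes took 16.8 to 19.7% of counts in the replicate-3 libraries of the 9 groups other than ND, RA and Sorb300, and 11.6 to 15.2% in their replicate-1 and replicate-2 libraries. In 33 of 36 libraries the deviation from the group mean correlated best with libraries of the same replicate number.

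**Figure D1:**
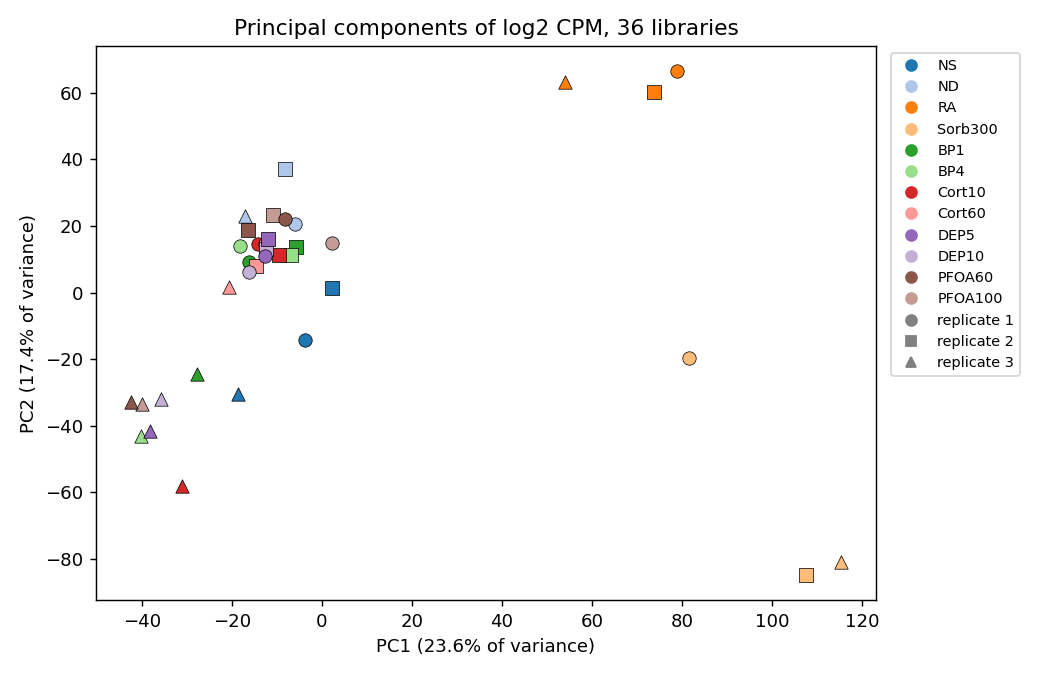
Principal components of log2 CPM for the 36 libraries. The first component (horizontal, 23.6% of variance) is plotted against the second (vertical, 17.4%), with 1 point per library, colour for the group and marker shape for the replicate number. RA and Sorb300 libraries lie away from the others, and Sorb300 library 1 lies apart from Sorb300 libraries 2 and 3.

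Withdrawal of LIF lowered the genes of naive pluripotency, the ground state that LIF maintains. Socs3, a feedback inhibitor and direct target of LIF signalling, fell 6.74-fold, from 194 ± 37.6 CPM in NS to 28.8 ± 5.19 CPM in ND (log2 fold change -2.75, SE 0.38, adjusted p = 0.000113). The transcription factors Tcfcp2l1 (4.53-fold, adjusted p = 0.000113), Tbx3 (4.86-fold, adjusted p = 0.000849), Klf4 (3.83-fold, adjusted p = 0.000849) and Esrrb (3.07-fold, adjusted p = 0.000849) fell with it. Tcl1 fell as well (3.79-fold, adjusted p = 0.000355). Of the 20 measured members of the naive list, 9 fell and 0 rose (18 fell when adjusted over the list alone). The list moved down in camera (adjusted p = 1.45e-31, and adjusted p = 0.000511 with an estimated correlation). Eomes, a T-box factor of early mesendoderm and trophoblast, had the largest rise among the named genes, 8.98-fold to 10.8 ± 5.87 CPM (log2 fold change 3.17, SE 0.66, adjusted p = 0.00972).

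No member of the core pluripotency list passed the test in ND: 0 of 12 rose or fell, and 0 when adjusted over the list alone. Pou5f1, which encodes Oct4, stood at 18.2 ± 3.65 CPM in ND and 29.4 ± 5.44 CPM in NS (log2 fold change -0.70, SE 0.34, adjusted p = 0.384). The formative and primed list moved up in camera (adjusted p = 1.79e-06, but adjusted p = 0.198 with an estimated correlation). Of its 15 members 0 passed over all genes and 6 rose when adjusted over the list alone. Among them the de novo DNA methyltransferase Dnmt3b stood 2.75-fold higher (1256 ± 284 against 457 ± 403 CPM, adjusted p = 0.0625) and Sox3 3.57-fold higher (adjusted p = 0.0628). The NS libraries spread at Dnmt3b (919, 172 and 281 CPM in libraries 1, 2 and 3). With the replicate number as a block, 8 of the 15 rose and the list call held (adjusted p = 0.0316 with an estimated correlation). In that fit Dnmt3b (adjusted p = 0.0147), Sox3 (adjusted p = 0.0207) and Lin28b (adjusted p = 0.00501) rose, the core gene Tdgf1 fell (adjusted p = 0.00257), and 13 of the 20 naive members fell.

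Several genes outside these lists were also among the largest changes in ND. Ppp4r4 rose 4.69-fold, Enpp2, which encodes the secreted lysophospholipase autotaxin, 4.58-fold, Pphln1 4.28-fold, Fign 3.63-fold and the transcription factor gene Myb 3.54-fold. Their adjusted p lay between 0.02 and 0.0418. Enpp2 stood at 58.8, 2.46 and 13.4 CPM in NS libraries 1, 2 and 3, and its rise passed the test when NS library 1 was left out (log2 fold change 3.82 instead of 2.19) but not when any other single library was. Myb went to a log2 fold change of 2.87 from 1.83 without NS library 1. Mylpf fell 7.74-fold to 22.0 ± 4.06 CPM (adjusted p = 0.000113), Cidea 7.11-fold (adjusted p = 0.00316), Myo1f 9.54-fold (adjusted p = 0.0358) and Spink3 8.69-fold (adjusted p = 0.0473). Of the integrated stress response list, 4 of 28 members fell over all genes and when adjusted over the list alone, and 5 fell and 1 rose with the replicate number as a block (camera adjusted p = 0.000131, adjusted p = 0.198 with an estimated correlation). Among them were the amino acid synthesis gene Asns (1.84-fold, adjusted p = 0.0148) and Mthfd2 (1.85-fold, adjusted p = 0.0217). Of 14 trophoblast genes Eomes rose and Tcfap2c fell 3.18-fold (adjusted p = 0.000113), with the same count when adjusted over the list alone (camera adjusted p = 0.0399, adjusted p = 0.271 with an estimated correlation).

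The retinoid list, genes that retinoic acid is known to induce, was lower in ND than in NS (camera adjusted p = 2.8e-06, but adjusted p = 0.084 with an estimated correlation). Of its 22 measured members 4 fell and 0 rose (9 fell when adjusted over the list alone, and 7 fell over all genes with the replicate number as a block). They included Stra8, an inducer of meiosis, 23.1-fold (adjusted p = 0.0141), and the homeobox gene Hoxb4 (adjusted p = 0.0263). The NS libraries differed among themselves at these genes: Stra8 stood at 8.64 CPM in NS library 1, 232 CPM in library 2 and 129 CPM in library 3. On leaving out 1 library, Stra8 lost the call in 4 of 6 fits (without NS library 2, at a log2 fold change of -3.67 instead of -4.53, and without each ND library). Hoxb4 lost it in 5 (without NS library 2, at -2.97 instead of -4.05, NS library 3 and each ND library). Stra8 was also the member that fell among 13 germline genes (5 fell and 1 rose when adjusted over the list alone, and 4 fell over all genes with the block). The germline list had a camera adjusted p = 0.00834 and adjusted p = 0.295 with an estimated correlation.

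Other lists moved in camera in ND without a called member in the fit without a block, and each lost the call with an estimated correlation. These were oxidative phosphorylation (camera adjusted p = 2.96e-05, adjusted p = 0.434 with an estimated correlation, 0 members when adjusted over the list alone) and fatty acid oxidation (0.00688, and adjusted p = 0.174 with an estimated correlation, 1 member fell when adjusted over the list alone). G1 and S phase genes were lower as well (0.018, and adjusted p = 0.296 with an estimated correlation, 2 members fell when adjusted over the list alone). CDK inhibitors were lower (0.0444, and adjusted p = 0.198 with an estimated correlation, 3 members fell when adjusted over the list alone). Interferon response genes were higher (0.0143, and adjusted p = 0.198 with an estimated correlation, 2 members rose when adjusted over the list alone). With the replicate number as a block, 2 members passed over all genes in each of these 5 lists, falling in the first 4 and rising in the last. Cytosolic ribosomal protein genes, whose share also differed between replicate numbers, had 2 of 80 members fall, Rpl10l and Rpl39l, with 2 when adjusted over the list alone (camera adjusted p = 8.61e-07, adjusted p = 0.56 with an estimated correlation).

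In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 35 genes higher and 126 lower in ND than in NS, out of 13498 tested. The authors' deposited table lists 257 genes at FDR under 0.05. With the replicate number as a block the test called 552 genes (212 higher and 340 lower), with all 161 among them. The count rested on single libraries: it was 312 without NS library 1, 32 without NS library 2, 36 without NS library 3, 75 without ND library 1, 34 without ND library 2 and 42 without ND library 3. It was 42 without the replicate-3 libraries of every group and 1 without NS libraries 2 and 3. Of the 25 called genes chosen for naming in ND, 17 lost the call on leaving out at least 1 library, and Socs3, Tcfcp2l1, Tbx3, Klf4, Esrrb, Tcl1, Mylpf and Tcfap2c did not. Camera calls ended without NS library 2 for CDK inhibitors, interferon response, germline and trophoblast genes. They also ended without ND library 1 (germline), ND library 2 (trophoblast), and NS library 1 or ND library 3 (G1 and S phase). The naive call held in all 6 fits with an estimated correlation too.

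Retinoic acid without LIF switched on a large set of developmental genes. Of the 22 retinoid list members 21 rose (21 when adjusted over the list alone), with a camera adjusted p = 7.15e-25 and adjusted p = 2.42e-07 with an estimated correlation. The homeobox gene Meis1 rose 90.8-fold to 107 ± 8.57 CPM (log2 fold change 6.50, SE 0.69, adjusted p = 1.75e-08), and Meis2 36.1-fold to 271 ± 27.1 CPM. The nuclear receptor gene Nr2f2 rose 202-fold to 166 ± 84.2 CPM, Tshz1 64.3-fold, Hoxb4 29.8-fold and Crabp2, which encodes a retinoic acid carrier protein, 6.98-fold. The NS libraries spread here too, with Meis2 at 1.66, 12.8 and 7.46 CPM in libraries 1, 2 and 3. Without NS library 2 the log2 fold changes rose from 6.50 to 7.96 for Meis1, 5.17 to 5.90 for Meis2, 7.66 to 8.60 for Nr2f2 and 4.90 to 6.03 for Hoxb4. Several genes had no count in any NS library. Against 3 counts over the NS group, Hoxc5 was at least 104-fold higher, Ttr, which encodes the thyroid hormone and retinol carrier transthyretin, at least 96.5-fold, and Osr1 at least 75.9-fold. The insulin gene Ins2 was at least 66.8-fold higher, Shisa3 at least 61.8-fold and the Wnt antagonist gene Dkk1 at least 61.5-fold. Shisa3 stood at 29.1, 8.88 and 8.73 CPM in RA libraries 1, 2 and 3, and its fitted log2 fold change went from 9.14 to 8.30 without RA library 1.

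Pluripotency genes fell in RA. Of 20 naive genes 14 fell and 1 rose (17 fell and 1 rose when adjusted over the list alone; adjusted p = 0.00709 with an estimated correlation). Fgf4 was down 14.4-fold, Tcl1 13.7-fold, Esrrb 7.65-fold, Nanog 4.98-fold, Tcfcp2l1 4.52-fold and Pecam1 4.28-fold. Of 12 core genes 6 fell and 0 rose (6 when adjusted over the list alone; adjusted p = 0.00709 with an estimated correlation). Tdgf1, which encodes a Nodal co-receptor, fell 32.7-fold from 921 ± 258 CPM, Pou5f1 14.5-fold, Utf1 9.17-fold, Sox2 4.57-fold, Epcam 2.68-fold and Dppa4 1.62-fold. The formative and primed list did not pass as a group (camera adjusted p = 0.196), with 3 members up and 7 down over all genes and when adjusted over the list alone. Sox4 rose 4.69-fold and the cadherin gene Cdh2 5.15-fold, while Otx2 fell 32.2-fold, Tcf15 7.10-fold, Dnmt3b 5.39-fold and Dnmt3a 1.89-fold. The size of 2 of these falls depended on which NS libraries were used. Otx2 stood at 486, 24.6 and 47 CPM in NS libraries 1, 2 and 3 and Dnmt3b at 919, 172 and 281 CPM. Without NS library 1 the log2 fold change was -2.58 instead of -5.01 for Otx2 (adjusted p = 0.0103) and -1.36 instead of -2.43 for Dnmt3b (adjusted p = 0.00559). That library was not the odd one at Otx2 in BP1, BP4, Cort10, Cort60, DEP5 and DEP10. Against it alone, their Otx2 log2 fold changes were -0.21 to -0.50, nearer to it than to NS libraries 2 and 3. Klk13 had no count in RA and was at least 63.1-fold lower, and Enpp2 (87.7-fold), Itgb7 (63.5-fold) and Dpys (28.8-fold) were the other large falls. For Enpp2 the log2 fold change went from -6.46 to -4.78 without NS library 1, and for Dpys from -4.85 to -6.48 without RA library 3.

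Markers of extraembryonic and mesenchymal cell types rose in RA. Of 21 extraembryonic endoderm genes 17 rose (18 when adjusted over the list alone; adjusted p = 0.0171 with an estimated correlation). Among them were the endocytic adaptor gene Dab2 (8.87-fold to 103 ± 34.1 CPM) and the basement membrane collagen gene Col4a2 (11.1-fold). Of 14 trophoblast genes 9 rose and 1 fell (11 rose and 1 fell when adjusted over the list alone; adjusted p = 0.012 with an estimated correlation). They included the keratin genes Krt18 (6.53-fold to 764 ± 239 CPM) and Krt8 (8.90-fold) and the transcription factor gene Gata3 (12.6-fold). Of 12 fibroblast and feeder markers 9 rose and 1 fell, with the same count when adjusted over the list alone (adjusted p = 0.00505 with an estimated correlation). The fibrillar collagen genes Col1a2 and Col3a1 rose 13.8-fold and 41.9-fold and the surface antigen gene Thy1 fell 6.33-fold. Without NS library 2 the log2 fold change went from 5.39 to 9.96 for Col3a1, 3.78 to 4.81 for Col1a2 and 4.48 to 5.13 for Igf2. Of 17 imprinted genes 10 rose (10 when adjusted over the list alone; adjusted p = 4.23e-05 with an estimated correlation), led by Igf2, a growth factor gene, 22.3-fold to 1751 ± 569 CPM, Peg3 11.8-fold and Peg10 8.02-fold. Of 11 genes of the two-cell-like state 8 rose (10 when adjusted over the list alone; camera adjusted p = 0.000505, adjusted p = 0.213 with an estimated correlation). Zscan4d rose 20.5-fold, Dub1 11.5-fold and Zfp352 10.3-fold, and without NS library 3 the log2 fold changes of Zscan4d and Zfp352 went from 4.36 to 5.68 and from 3.36 to 4.45.

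Metabolic, stress and proliferation genes were lower in RA. Of the integrated stress response list 16 of 28 fell and 2 rose (18 and 2 when adjusted over the list alone; adjusted p = 0.0171 with an estimated correlation). They included the serine synthesis gene Psat1 (4.90-fold), Pck2 (5.28-fold) and Asns (3.15-fold). For the next lists camera passed but the call was lost with an estimated correlation. Of 19 glycolysis and hypoxia genes 12 fell (14 when adjusted over the list alone; camera adjusted p = 1.97e-09, adjusted p = 0.0723 with an estimated correlation). Pfkp was down 7.93-fold, Ldha 3.89-fold and Pkm2 3.46-fold. Of 22 G1 and S phase genes 14 fell and 1 rose (14 and 2 when adjusted over the list alone; adjusted p = 0.0717 with an estimated correlation). Among them were the replicative helicase genes Mcm6 (2.36-fold) and Mcm5 (2.60-fold) and Cdc45 (2.48-fold). Of 24 G2 and M phase genes 8 fell (9 when adjusted over the list alone; adjusted p = 0.14 with an estimated correlation). Ube2c was down 2.57-fold, Ccnb1 1.69-fold and Ccnb2 1.78-fold. Cholesterol synthesis had 10 of 24 members fall (11 when adjusted over the list alone; adjusted p = 0.0723 with an estimated correlation) and NRF2 oxidative stress 11 of 21 (11 fell and 1 rose when adjusted over the list alone; adjusted p = 0.0876 with an estimated correlation). In oxidative phosphorylation 15 of 24 fell (17 when adjusted over the list alone; adjusted p = 0.312 with an estimated correlation) and cytosolic ribosomal proteins 69 of 80 (74 when adjusted over the list alone; adjusted p = 0.221 with an estimated correlation). Fdps fell 2.63-fold, Gsta4 3.72-fold, Atp5b 2.37-fold and Rpl3 2.65-fold.

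The test called 1390 genes higher and 1869 lower in RA than in NS, and the authors' deposited table lists 3153. The balance depended on the scaling of libraries, with 1639 higher and 1524 lower with RLE size factors. The count was 1886 without NS library 3, 2037 without RA library 1 and 1410 without NS libraries 2 and 3. Of the 72 called genes chosen for naming in RA, 15 moved by over 1.5 times on leaving out 1 library and 0 lost the call.

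RA and ND both lacked LIF, so their comparison holds LIF withdrawal constant and isolates the added retinoic acid. Hox genes showed the largest rises: against 3 counts over the ND group Hoxb5 was at least 402-fold, Hoxc5 at least 171-fold and Hoxb8 at least 170-fold higher, and Hoxa5, with 1 count in ND, stood 1500-fold higher (95% counting interval 269 to 59300). That count lay in ND library 3, without which the fitted log2 fold change went from 9.90 to 11.5. Of 22 retinoid genes 21 rose (22 when adjusted over the list alone; adjusted p = 2.98e-07 with an estimated correlation), including Hoxb4 (495-fold), Meis1 (184-fold), Meis2 (153-fold), Tshz1 (149-fold) and Nr2f2 (83.4-fold; log2 fold change 6.999 instead of 6.381 without ND library 3). Otx2, a transcription factor of the formative epiblast, fell 124-fold from 714 ± 140 CPM in ND to 6.21 ± 4.47 CPM in RA (log2 fold change -6.95, SE 0.99, adjusted p = 1.85e-05; -7.56 without RA library 2). Dnmt3b fell 14.8-fold and Dnmt3a 2.43-fold, and of 15 formative and primed genes 9 fell and 2 rose (10 and 2 when adjusted over the list alone; camera adjusted p = 1.46e-05, adjusted p = 0.165 with an estimated correlation).

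Of 12 core genes 5 fell and 1 rose (7 and 1 when adjusted over the list alone; adjusted p = 0.0046 with an estimated correlation). Tdgf1 was down 16.03-fold (log2 fold change -3.398 instead of -4.003 without ND library 1), Utf1 10.9-fold and Epcam 3.87-fold. Extraembryonic endoderm genes rose in 18 of 21 cases (18 when adjusted over the list alone; adjusted p = 0.0046 with an estimated correlation) and trophoblast genes in 11 of 14 with 1 fall (12 and 1 when adjusted over the list alone; adjusted p = 0.00135 with an estimated correlation). Imprinted genes rose in 10 of 17 (10 when adjusted over the list alone; adjusted p = 1.35e-05 with an estimated correlation) and fibroblast markers in 8 of 12 with 1 fall (the same when adjusted over the list alone; adjusted p = 0.0046 with an estimated correlation). Krt8 rose 10.5-fold, Gata3 20.9-fold, Lama1 10.4-fold, Igf2 59.5-fold and Col1a2 20.01-fold. Without ND library 3 the log2 fold change of Gata3 was 5.26 instead of 4.38. Of 5 CDK inhibitor genes Cdkn1c (5.83-fold), Cdkn2a (5.13-fold) and Cdkn2b (2.92-fold) rose (3 when adjusted over the list alone; adjusted p = 0.0402 with an estimated correlation). The list call held whichever single library was left out, but Cdkn2b lost its call in 5 of the 6 fits (adjusted p = 0.233 without RA library 1) and kept it without RA library 2. Of 11 two-cell-like genes 9 rose (10 rose and 1 fell when adjusted over the list alone; adjusted p = 0.0911 with an estimated correlation), among them Usp17l5 (56.8-fold).

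The lists that moved in camera and lost the call with an estimated correlation in RA against ND were mostly lower. Integrated stress response genes fell in 15 of 28 cases with 1 rise (16 and 2 when adjusted over the list alone; adjusted p = 0.0919 with an estimated correlation) and glycolysis genes in 10 of 19 (12 when adjusted over the list alone; adjusted p = 0.0921 with an estimated correlation). G2 and M phase genes fell in 8 of 24 (12 when adjusted over the list alone; adjusted p = 0.0621 with an estimated correlation) and G1 and S phase genes in 10 of 22 with 2 rises (11 and 3 when adjusted over the list alone; adjusted p = 0.198 with an estimated correlation). NRF2 genes fell in 8 of 21 cases (8 when adjusted over the list alone; adjusted p = 0.0827 with an estimated correlation), led by Cbr3 (12.7-fold) and Gclm, which encodes a subunit of glutathione synthesis (2.72-fold). Cholesterol genes fell in 6 of 24 cases with 1 rise, that of Ebp, 2.57-fold (7 falls and 1 rise when adjusted over the list alone; adjusted p = 0.17 with an estimated correlation). Ribosomal protein genes fell in 26 of 80 with 1 rise (51 and 1 when adjusted over the list alone; adjusted p = 0.41 with an estimated correlation), and oxidative phosphorylation genes in 2 of 24 (0 when adjusted over the list alone; adjusted p = 0.556 with an estimated correlation). Of 4 aryl hydrocarbon receptor target genes Cyp1b1 (80.6-fold) and Tiparp (2.08-fold) rose (2 when adjusted over the list alone; adjusted p = 0.0911 with an estimated correlation). The camera call of that list ended whichever single library was left out (adjusted p between 0.0792 and 0.261), and the log2 fold change of Cyp1b1 went from 6.33 to 9.90 without ND library 1. The test called 1086 genes higher and 1364 lower in RA than in ND (1220 and 1102 with RLE size factors), and the count in all was 1509 without RA library 1 and 1613 without ND library 3. Of the 62 called genes chosen for naming in RA against ND, 8 moved by over 1.5 times and 5 lost the call on leaving out at least 1 library. Camera calls ended also for cholesterol synthesis without RA library 3, G1 and S phase without ND library 1 and oxidative phosphorylation without ND library 3.

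**Figure D2:**
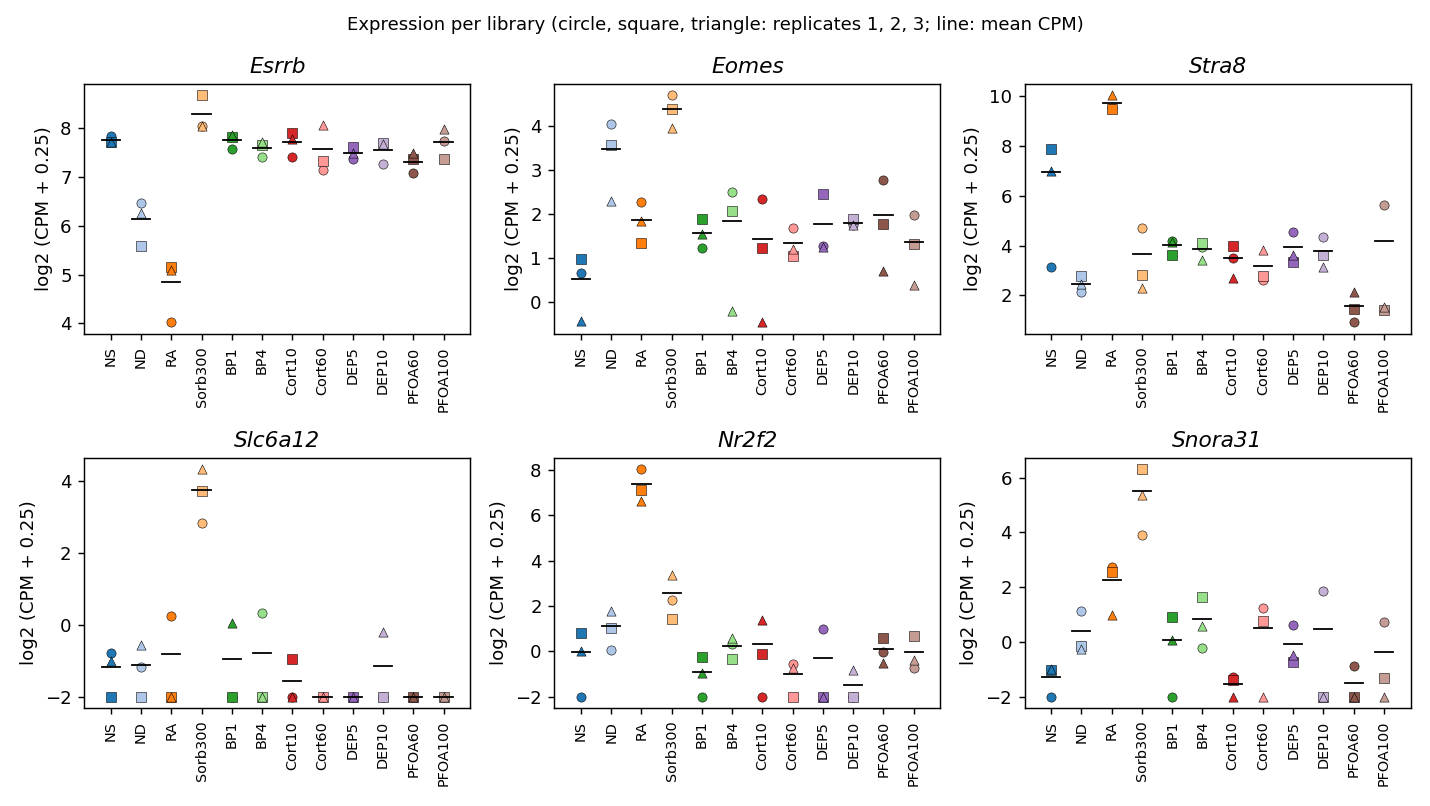
CPM of Esrrb, Eomes, Stra8, Slc6a12, Nr2f2 and Snora31 in every library, as log2 of CPM plus 0.25 (vertical) by group (horizontal). Points are libraries, marker shapes are replicate numbers and bars are log2 of the group's mean CPM plus 0.25. Esrrb is lowest in RA and ND, Eomes stands at 10.8 CPM in ND and 20.5 CPM in Sorb300 against 1.18 CPM in NS, and Stra8 in NS spans 8.64 to 232 CPM.

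Hyperosmotic sorbitol was given with LIF present. Slc6a12, the betaine transporter gene, stood 62.8-fold above NS (95% counting interval 17.1 to 524, with 2 counts over the NS group; adjusted p = 0.00228). The amino acid transporter gene Slc38a2 rose 2.83-fold (adjusted p = 0.0103) and the taurine transporter gene Slc6a6 1.59-fold (adjusted p = 0.0118), and both lost the call without NS library 2 or NS library 3, Slc38a2 also without Sorb300 library 1. The heat shock gene Hspa1b rose 6.48-fold and the aldose reductase gene Akr1b3 2.39-fold, while Hspa4l fell 2.33-fold. Akr1b3 lost the call in 4 of 6 fits with a library left out and Hspa4l in 3, and the log2 fold change of Hspa4l went from -1.22 to -2.62 without Sorb300 library 1. In all, 5 of 10 osmotic genes rose and 1 fell (6 and 1 when adjusted over the list alone), but the list as a group did not pass camera (adjusted p = 0.0521). Trophoblast genes rose in 10 of 14 cases with 0 falls (11 when adjusted over the list alone; camera adjusted p = 1.39e-05, adjusted p = 0.0692 with an estimated correlation). Hand1 rose 20.02-fold to 180.3 ± 69.9 CPM (log2 fold change 4.32, SE 0.53, adjusted p = 4.33e-07), Eomes 17.2-fold and Gata3 14.2-fold.

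Pluripotency genes moved in both directions in Sorb300 and the lists did not pass as groups. Of 20 naive genes 5 rose and 1 fell (6 and 1 when adjusted over the list alone; camera adjusted p = 0.202). Tbx3 rose 4.96-fold to 563 ± 2.11 CPM, Nr0b1 3.44-fold, Klf5 2.66-fold, Nr5a2 2.46-fold and Klf4 1.98-fold, and Dppa3 fell 3.97-fold. Of 12 core genes 4 rose and 2 fell (5 and 2 when adjusted over the list alone; camera adjusted p = 0.236). Zfp296 rose 8.22-fold, Sall4 3.14-fold, Dppa2 2.38-fold and Utf1 1.78-fold, and Epcam fell 2.23-fold and Tdgf1 2.36-fold. Of 15 formative genes 0 rose and 2 fell (1 when adjusted over the list alone; camera adjusted p = 0.388), Lin28b 2.80-fold and Dnmt3a 1.46-fold. On leaving out 1 library the call was lost in 5 of 6 fits for Nr0b1, 4 for Utf1 and Dnmt3a, 3 for Klf4 and Dppa2, 2 for Lin28b and 1 for Nr5a2 and Tdgf1. Cholesterol synthesis genes fell in 12 of 24 cases with 3 rises (13 and 3 when adjusted over the list alone; camera adjusted p = 0.000883, a call lost without Sorb300 library 1, and adjusted p = 0.212 with an estimated correlation). The sterol sensor gene Insig1 fell 6.78-fold, Cyp51 3.54-fold and Sc4mol 3.40-fold. Ribosomal protein genes fell in 38 of 80 cases with 1 rise (41 and 1 when adjusted over the list alone; camera adjusted p = 2e-08, adjusted p = 0.594 with an estimated correlation).

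Of the 6 largest rises named in Sorb300, 5 were of small nucleolar RNA genes, which guide chemical modification of ribosomal RNA. Snora5c stood 891-fold (95% counting interval 246 to 7360), Snora15 858-fold (154 to 33900), Snora47 471-fold (84.2 to 18700) and Snora31 234-fold (64.4 to 1940) above NS, where each had 1 or 2 counts over the group. Single libraries moved the fitted log2 fold changes. They went from 9.75 to 12.6 for Snora5c and 9.41 to 11.5 for Snora15 without NS library 3, which held their counts in NS, 8.61 to 10.7 for Snora47 without NS library 2, and 7.77 to 7.06 for Snora31 without Sorb300 library 2. Snora41 rose 129-fold to 279 ± 228 CPM (adjusted p = 0.000142; log2 fold change 8.56 instead of 7.01 without NS library 2). Of 77 tested small nucleolar RNA genes, a set chosen after these values were seen, 60 rose and 0 fell. Taken by gene name, the set held Scarna genes besides Snora and Snord genes. Of the 77, 67 lie inside a tested host gene, and the strand used in counting is not given in the sources used here. The homeobox gene Evx1 had no count in NS and was at least 29.9-fold higher. The immunoproteasome gene Psmb8 stood 195-fold lower (53.5 to 1610; fitted log2 fold change -6.66 instead of -7.51 without NS library 1), and the guanylate binding protein genes Gbp2 and Gbp1 fell 51.4-fold and 35.0-fold. The interferon list as a group did not pass (camera adjusted p = 0.161; 4 of 15 fell and 1 rose, the same when adjusted over the list alone). Txnip, a regulator of glucose uptake, fell 25.5-fold from 1124 ± 505 CPM, Atp10a 24.7-fold and Stc1 22.6-fold, the last losing the call whichever single library was left out (log2 fold change -3.72 instead of -4.50 without NS library 1). The log2 fold change of Atp10a went from -4.62 to -8.57 without Sorb300 library 1.

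The test called 2044 genes higher and 2058 lower in Sorb300 than in NS (2234 and 1926 with RLE size factors), and the authors' deposited table lists 4011. The count was 1513 without NS libraries 2 and 3 and 2284 with only the compared groups in the fit. Of the 41 called genes chosen for naming in Sorb300, 9 moved by over 1.5 times and 13 lost the call on leaving out at least 1 library.

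**Figure D3:**
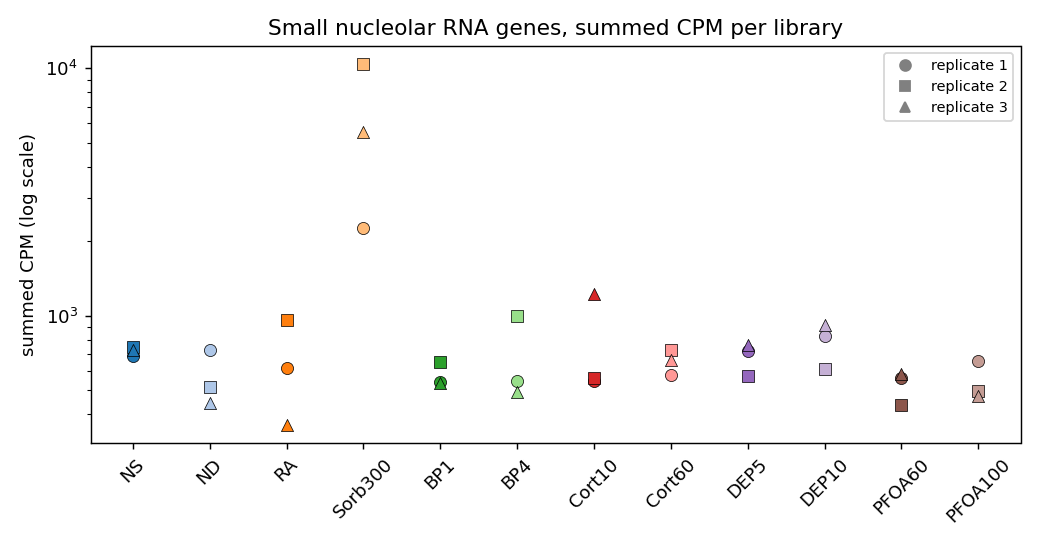
Summed CPM of the small nucleolar RNA genes in each library (vertical, log scale) by group (horizontal), with 1 point per library and marker shapes for the replicate number. The Sorb300 libraries stand at 2260, 10400 and 5520 CPM, the NS libraries at 691, 748 and 729 CPM and all other libraries between 363 and 1230 CPM.

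BP, tested at both doses for its effect on growing stem cells, gave no called gene by edgeR's quasi-likelihood test. The aryl hydrocarbon receptor target Tiparp stood at 53.8 ± 8.52 CPM in BP1 and 61.1 ± 16.9 CPM in BP4 against 39.1 ± 14.3 CPM in NS (log2 fold changes 0.45, SE 0.26, and 0.65, SE 0.26, both with adjusted p = 1.0). Cyp1b1 was near the floor, with ratios to NS of 2.18 (95% counting interval 0.544 to 12.5) in BP1 and 3.02 (0.777 to 17.1) in BP4. Nqo1 stood at log2 fold changes of -0.51 (SE 0.53) and -0.63 (SE 0.56). Among p53 targets Eda2r stood at 44.3 ± 3.52 and 42.6 ± 5.36 CPM against 26.6 ± 7.10 CPM. Btg2 stood at 107 ± 36.6 and 107 ± 39.2 CPM against 71.8 ± 16.7 CPM, and Trp53inp1 at 296 ± 15.9 and 307 ± 17.3 CPM against 208 ± 81.5 CPM. Neither list had a called member in either dose, 0 when adjusted over the list alone, nor a camera call (adjusted p = 0.254 and 0.436 for the receptor list, 0.0544 and 0.284 for p53). With the replicate number as a block the p53 list passed camera in BP1 (adjusted p = 0.0381, but adjusted p = 0.335 with an estimated correlation).

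The pluripotency genes also stayed under the threshold with BP. Nanog stood at 323 ± 77.7 CPM in BP1 and 272 ± 39.5 CPM in BP4 against 423 ± 123 CPM in NS, and Dppa2 at 26.04 ± 10.04 and 24.5 ± 8.17 CPM against 51.4 ± 19.2 CPM. The retinoid list was lower in camera in both (adjusted p = 0.00127 and 0.00177 with an estimated correlation), with 9 and 10 of 22 members down when adjusted over the list alone and 0 over all genes, against NS libraries that differed at these genes. Each of these 2 calls held whichever single library was left out. NS libraries 2 and 3 both stood above library 1 at these genes, so this always kept a high NS library. The list was not tested without both. edgeR's quasi-likelihood test called 0 genes in BP1 and 0 in BP4, with 351 and 458 genes at an unadjusted p under 0.05. Without NS library 1 it called 5 and 6. Its likelihood ratio test called 4 and 3, DESeq2 1 and 2, and the authors' deposited tables list 1 and 2. Counts were simulated for BP4 against NS over 13057 genes, with each gene's mean taken over all libraries. Changed genes were drawn from above a minimum mean CPM, so the shares recovered leave out the least expressed genes. The test recovered 4% of genes changed 1.5-fold, 20% of those changed 2-fold, 72% at 4-fold and 92% at 8-fold. Smaller changes were thus mostly not detectable at this depth and spread. BP4 against BP1 gave 0 calls by edgeR's quasi-likelihood test, its likelihood ratio test and DESeq2 (83 genes at an unadjusted p under 0.05), with Tiparp at a log2 difference of 0.20 (SE 0.26).

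Cortisol, a glucocorticoid, left the glucocorticoid response list without a called member at either dose (0 of 16, and 0 when adjusted over the list alone; camera adjusted p = 0.649 in Cort10 and 0.183 in Cort60). Zbtb16 stood 6.26-fold (95% counting interval 0.868 to 274) and 9.14-fold (1.27 to 400) above NS, from 1 count over the NS group. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, stood at 25.2 ± 9.81 CPM in Cort60 against 15.95 ± 0.211 CPM in NS (log2 fold change 0.68, SE 0.40, adjusted p = 0.828), and Fkbp5 at 83.8 ± 3.42 against 102 ± 9.71 CPM (adjusted p = 0.854). Nanog stood at 263 ± 74.7 CPM in Cort10 and 253 ± 41.3 CPM in Cort60 against 423 ± 123 CPM in NS. Fibroblast and feeder markers were lower as a group (adjusted p = 0.00726 and 0.0233 with an estimated correlation), with 2 of 12 down at each dose when adjusted over the list alone and 0 over all genes. The NS libraries differed at these markers too (Col1a1 at 17.95, 48.95 and 17.16 CPM in NS libraries 1, 2 and 3), and without NS library 2 both calls were lost (adjusted p = 0.128 and 0.153 with an estimated correlation). The retinoid list was lower too (adjusted p = 0.00343 and 0.0233 with an estimated correlation; 12 and 5 of 22 when adjusted over the list alone, 0 over all genes). In Cort60 the retinoid call was lost without NS library 2 (adjusted p = 0.153 with an estimated correlation) and both list calls without Cort60 library 2 or 3.

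The quasi-likelihood test of edgeR called 0 genes in Cort10 (520 at an unadjusted p under 0.05), as did its likelihood ratio test and DESeq2, and it called 0 in Cort60 (817 at an unadjusted p under 0.05). In Cort60 the likelihood ratio test called 16, DESeq2 10 and the authors' deposited table lists 9. Without NS library 1 the quasi-likelihood test called 6 in Cort10 and 17 in Cort60. Cort60 against Cort10 gave 0 calls by all 3 tests (291 genes at an unadjusted p under 0.05), with Pdk4, a glucocorticoid-induced kinase gene, at 3.13 ± 1.46 against 1.19 ± 0.76 CPM (log2 difference 1.54, SE 0.98, adjusted p = 1.0).

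DEP gave no called gene at either dose by edgeR's quasi-likelihood test, its likelihood ratio test or DESeq2. Nanog stood at 273 ± 77.1 CPM in DEP5 and 264 ± 16.7 CPM in DEP10 against 423 ± 123 CPM in NS (log2 fold changes -0.63 and -0.68, SE 0.30 each), Dppa2 at 23.6 ± 7.42 and 22.6 ± 3.15 CPM against 51.4 ± 19.2 CPM, and Dppa5a at 226 ± 166 CPM in DEP10 against 555 ± 223 CPM, all with adjusted p = 1.0. The naive list was lower in camera (adjusted p = 0.00727 and 0.00193) with 0 of 20 members called over all genes or when adjusted over the list alone. Its call was lost with an estimated correlation (adjusted p = 0.519 and adjusted p = 0.415 with an estimated correlation). The retinoid list was lower too (9 and 10 of 22 members when adjusted over the list alone, 0 over all genes; adjusted p = 0.0192 and 0.0555 with an estimated correlation, and for DEP5 adjusted p = 0.056 with an estimated correlation and the replicate number as a block). The DEP5 call was also lost without NS library 2 (adjusted p = 0.225 with an estimated correlation), NS library 3 or DEP5 library 2 or 3. The p53 list was higher in camera in DEP10 (adjusted p = 0.00689, adjusted p = 0.415 with an estimated correlation; 0 of 28 over all genes and when adjusted over the list alone). edgeR's quasi-likelihood test, its likelihood ratio test and DESeq2 each called 0 genes in DEP5 (505 at an unadjusted p under 0.05 in the first), in DEP10 (614) and in DEP10 against DEP5 (164), and the authors' deposited tables list 0 at both doses. Without NS library 1 the quasi-likelihood test called 1 gene in DEP5 and 4 in DEP10.

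PFOA at 60 µM was the toxicant condition with called genes by edgeR's quasi-likelihood test: 1 rose and 9 fell. Stra8 fell 49.7-fold to 2.74 ± 1.26 CPM (log2 fold change -5.63, SE 1.04, adjusted p = 0.0449), from NS libraries at 8.64, 232 and 129 CPM (log2 fold change -4.79 without NS library 2). The collagen gene Col1a1 fell 5.995-fold from NS libraries at 17.95, 48.95 and 17.16 CPM (log2 fold change -1.89 instead of -2.58 without NS library 2), Mras 5.64-fold, the oocyte factor gene Ooep 4.82-fold to 31.1 ± 13.6 CPM, Mylpf 4.06-fold and Rpl10l 3.89-fold, each with adjusted p = 0.0449. Named after their values were seen, the other called genes were Thsd7a, which rose from 0.69 ± 0.567 to 7.81 ± 2.78 CPM (adjusted p = 0.0275; log2 fold change 4.31 instead of 3.54 without NS library 1), and Krt23, Krt79 (no count in PFOA60, at least 14.9-fold lower) and Rpl39l, which fell (adjusted p = 0.0449; Krt23 at a log2 fold change of -3.30 instead of -3.94 without NS library 3). Each of the 10 lost the call on leaving out at least 1 library.

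Of 20 naive genes 0 passed over all genes in PFOA60 and 4 fell when adjusted over the list alone (camera adjusted p = 2.86e-10, adjusted p = 0.0568 with an estimated correlation). Tcl1 stood at 34.1 ± 8.98 against 81.2 ± 24.5 CPM, Nanog at 194 ± 16.2 against 423 ± 123 CPM and Klf4 at 73.8 ± 8.74 against 155 ± 44.6 CPM. Of 11 two-cell-like genes 9 fell when adjusted over the list alone and 0 over all genes (adjusted p = 0.0568 with an estimated correlation). The retinoid list had 1 fall over all genes and 8 when adjusted over the list alone (adjusted p = 0.0568 with an estimated correlation). Fatty acid oxidation and PPAR genes had 0 calls of 23 over all genes and when adjusted over the list alone (camera adjusted p = 0.928). Cpt1a, the rate-limiting enzyme of mitochondrial fatty acid import, stood at 69.7 ± 9.30 against 42.1 ± 8.52 CPM (log2 fold change 0.73, SE 0.32, adjusted p = 0.587) and Acadl at 153 ± 29.8 against 103 ± 23.0 CPM. With the replicate number as a block the test called 47 genes (5 higher and 42 lower), Tcl1 among them (adjusted p = 0.0125). The count of 10 became 40 without NS library 1, 0 without NS library 2, NS library 3 or PFOA60 library 1, 1 without PFOA60 library 2 or 3, and 0 without the replicate-3 libraries of every group. DESeq2 called 80, the likelihood ratio test 104, and the authors' deposited table lists 60.

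At 100 µM PFOA no gene was called by edgeR's quasi-likelihood test (0, with 652 at an unadjusted p under 0.05) or DESeq2 (0), the likelihood ratio test called 2 and the authors' deposited table lists 1. Cpt1a stood at 63.8 ± 27.5 CPM and Acadl at 154 ± 59.0 CPM, with adjusted p = 0.995 for both, and the fatty acid oxidation list had 0 calls of 23 over all genes and when adjusted over the list alone (camera adjusted p = 0.69). Fibroblast and feeder markers were lower as a group (adjusted p = 0.014 with an estimated correlation; 2 of 12 when adjusted over the list alone, 0 over all genes). That call was lost without NS library 2 (adjusted p = 0.213 with an estimated correlation) and without PFOA100 library 3 (0.0726). The retinoid list was lower in camera, but not without NS library 2 (adjusted p = 0.329) or when the correlation was estimated (adjusted p = 0.206 with an estimated correlation; 4 of 22 when adjusted over the list alone, 0 over all genes). The count became 37 without PFOA100 library 1 and 1 without NS library 1. PFOA100 against PFOA60 gave 0 calls by the quasi-likelihood test, the likelihood ratio test and DESeq2 (250 genes at an unadjusted p under 0.05), with 7 of 11 two-cell-like genes higher when adjusted over the list alone and 0 over all genes (camera adjusted p = 4.19e-06, adjusted p = 0.431 with an estimated correlation). PFOA100 library 1 stood apart from libraries 2 and 3 (Nanog at 406, 188 and 202 CPM, Stra8 at 49.2, 2.37 and 2.64 CPM). Without it the two-cell-like genes were lower in PFOA100 than in PFOA60 and did not pass (camera adjusted p = 0.0729).

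Further lists passed camera in the toxicant groups and lost the call with an estimated correlation. Of all 68 camera calls in the 8 groups against NS, 19 held whichever single library was left out. G1 and S phase genes were lower than in NS in all 8 groups (camera adjusted p between 0.000683 and 0.0217, adjusted p between 0.233 and 0.415 with an estimated correlation). Of the 22 members 0 were called over all genes, and 1 fell when adjusted over the list alone, in DEP10. The naive list was lower in BP4, Cort10, Cort60 and PFOA100 too (camera adjusted p between 0.000301 and 0.0411, adjusted p between 0.33 and 0.539 with an estimated correlation), with 0 members called either way. Two-cell-like genes were lower in BP1, BP4, Cort10, Cort60, DEP10 and PFOA100 (camera adjusted p between 0.00607 and 0.044, adjusted p between 0.47 and 0.539 with an estimated correlation; 0 of 11 over all genes and when adjusted over the list alone). In BP4 that call ended with the replicate number as a block (adjusted p = 0.0627). Endoplasmic reticulum chaperone genes were lower in BP1, both cortisol doses, DEP10 and both PFOA doses (camera adjusted p between 0.0037 and 0.0364, adjusted p between 0.167 and 0.514 with an estimated correlation; 0 of 18 over all genes and when adjusted over the list alone).

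Fibroblast and feeder markers were lower in camera in BP1, BP4, DEP10 and PFOA60 as well (adjusted p between 0.12 and 0.317 with an estimated correlation; 2, 1, 1 and 2 of 12 fell when adjusted over the list alone, and Col1a1 over all genes in PFOA60). Each of these 4 camera calls was lost without NS library 2 (adjusted p between 0.245 and 0.36). Germline genes were lower in Cort10, PFOA60 and PFOA100 (adjusted p = 0.347, 0.148 and 0.617 with an estimated correlation; 1, 3 and 1 of 13 when adjusted over the list alone, and Stra8 over all genes in PFOA60). Extraembryonic endoderm genes were lower in Cort60, DEP10 and PFOA60 (adjusted p = 0.539, 0.495 and 0.387 with an estimated correlation; 0 of 21 either way). Interferon response genes were higher in Cort10, PFOA60 and PFOA100 (adjusted p = 0.347, 0.148 and 0.33 with an estimated correlation; 2, 0 and 0 of 15 when adjusted over the list alone), and in BP1 with the replicate number as a block (adjusted p = 0.0473, and 0.0896 without it). Oxidative phosphorylation genes were lower in BP1 and Cort60 (adjusted p = 0.608 and 0.58 with an estimated correlation; 0 of 24 either way), and in PFOA60 with the block (adjusted p = 0.0256, and 0.0978 without it).

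Ribosomal protein genes, whose share differed between replicate numbers, were lower in camera in Cort60, DEP10, PFOA60, PFOA100 and DEP10 against DEP5 (adjusted p between 0.705 and 0.963 with an estimated correlation; only Rpl10l and Rpl39l fell over all genes, in PFOA60). The direction rested on single libraries: it turned in 3 of 6 fits with a library left out for PFOA100 (median log2 fold change 0.092 without NS library 3, 0.034 without PFOA100 library 1 and 0.021 without PFOA100 library 2). For DEP10 against DEP5 it turned in 2, without DEP5 library 3 (0.215, with a camera call upward) and without DEP10 library 1. It turned in 1 fit each for Cort60 (0.026 without NS library 3) and PFOA60 (0.02 without PFOA60 library 1), and in DEP10 the call ended without NS library 3 and without DEP10 library 1 or 2. With the block they were lower also in BP1 (adjusted p = 0.00798, and 0.0544 without it) and in BP4 against BP1 (adjusted p = 0.0439, and 0.128 without it). G2 and M phase genes were higher in BP4 and PFOA60 (adjusted p = 0.377 and 0.401 with an estimated correlation; 0 of 24 either way). CDK inhibitor genes were lower in BP4 and Cort10 (adjusted p = 0.227 and 0.338 with an estimated correlation; 1 and 0 of 5 when adjusted over the list alone). Imprinted genes were lower in BP4, heat shock genes in Cort60, integrated stress response genes in DEP10 and glycolysis genes in PFOA100 (adjusted p = 0.286, 0.273, 0.495 and 0.617 with an estimated correlation; 2 of 17 imprinted genes and 0 of the others when adjusted over the list alone). Aryl hydrocarbon receptor targets were higher in PFOA100 (adjusted p = 0.206 with an estimated correlation; 1 of 4 when adjusted over the list alone), a camera call that ended whichever single library was left out (adjusted p between 0.221 and 0.412). Between the PFOA doses, naive, retinoid and germline genes were higher in PFOA100 (adjusted p = 0.431 each with an estimated correlation; 0 members either way; the naive and retinoid calls were lost without PFOA100 library 1 or PFOA60 library 1, and the germline call without PFOA100 library 3 or PFOA60 library 1 or 2), and formative genes with the block (adjusted p = 0.0154, and 0.0501 without it).

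The higher doses of the toxicants were chosen for equal growth suppression, so BP4, Cort60, DEP10 and PFOA100 were compared with each other in an F test. edgeR's quasi-likelihood F test called 0 genes (268 at an unadjusted p under 0.05), the likelihood ratio test 3 and DESeq2 0. Nanog, as an example, stood at 272 ± 39.5, 253 ± 41.3, 264 ± 16.7 and 265 ± 122 CPM in the 4 groups.

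All comparisons with NS share its 3 libraries, and so share part of their chance deviations. Across 13498 genes, which are not independent replicates, log2 fold changes of ND and RA correlated with r = 0.36. For ND and Sorb300 r was 0.09, and for RA and Sorb300 it was 0.35. In 20 simulations of unchanged groups, every library, NS included, was drawn anew around the NS mean with each gene's fitted spread. They gave mean values of 0.54, 0.52 and 0.51. The covariance was 0.371 against a simulated 0.197 for ND and RA, 0.0992 against 0.196 for ND and Sorb300 and 0.6 against 0.196 for RA and Sorb300. ND and RA had 60 genes lower in both (17.4 for independent lists) and 11 higher in both (3.6), with 17 opposite. RA and Sorb300 had 595 lower (285) and 373 higher (210), with 293 opposite. ND and Sorb300 had 17 lower (19.2) and 6 higher (5.3), with 54 opposite. Values for independent lists were not computed for the opposite counts, so these cannot be read as many or few. Among the toxicants r reached 0.67, between BP1 and BP4, where the simulations gave 0.51. The simulations held only that a drawn NS group was shared, and neither the values of the real NS libraries nor replicate sets. Libraries of the same number in BP1 and BP4 also correlated in their deviations from the group means (0.18, 0.32 and 0.47), which can raise r without any treatment effect. The 3 NS libraries are too few to split, and part of each excess may come from them or from replicate sets.

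The 35 genes higher and 126 lower in ND were used as a LIF withdrawal signature in the other conditions. Between doses, which share no NS library in their difference, the lower set stood higher in PFOA100 than in PFOA60 (mean log2 difference 0.33, 102 of 126 genes positive, camera adjusted p = 6.92e-11, adjusted p = 0.568 with an estimated correlation) and the higher set lower (mean -0.19, adjusted p = 0.00191, adjusted p = 0.629 with an estimated correlation). Without PFOA100 library 1 neither set passed (adjusted p = 0.333 for both), and the mean of the lower set was 0.011. The other 3 dose pairs gave no call with all libraries, but the lower set passed in 4 of their 18 fits with a library left out. It was lower in BP4 than in BP1 without BP4 library 3 (adjusted p = 0.00686) and in Cort60 than in Cort10 without Cort10 library 1 (0.00691) or Cort60 library 3 (0.00352), and higher in DEP10 than in DEP5 without DEP5 library 3 (0.00127). Against NS, simulated values come from other genes, those with the smallest p in each simulation's own ND against NS with drawn libraries. They hold neither the real NS libraries nor replicate sets, and numbers pair in ND and PFOA60 against NS. A gap from them thus does not show a treatment effect. In PFOA60 the lower set had a mean log2 fold change of -1.05 against a simulated -0.56, and the higher set 1.08 against a simulated 1.06. In BP1 the lower set stood at -0.56 against a simulated -0.55. In Sorb300 the sets stood away from the simulation, the lower set at 0.25 against -0.56 and the higher set at -0.32 against 1.12.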

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

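The test of genes high in RA for the retinoid pattern and the test of library depth for the replicate-3 pattern were chosen only after the results were seen, as were the set of small nucleolar RNA genes and the comparison of libraries within Sorb300.

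The retinoid list was lower in all 8 toxicant groups than in NS by camera, with NS libraries 2 and 3 above library 1 by a mean of 1.38 on the log2 scale over 22 genes. A difference between replicate sets is argued against: in the other 9 groups with LIF the same difference had a median of -0.03 (range -0.60 to 0.20), a ratio of -0.0181 to that in NS. RA material in NS libraries 2 and 3 stays open as part of the pattern. It would bring equal shares of the RA level, but 70 genes high in RA, outside the list, stood there at a median of 4.71% (61 above NS library 1) against 1.73% for 21 list members, a ratio of 2.72. With genes from 20 CPM in RA taken in, the median was 4.19% over 96 genes. Of these, 5 had no count in NS libraries 2 and 3 (Cyp1b1, Hoxc5, Osr1, Smoc2 and Ttr). A share of 4.71% would bring them 8.06 to 11.8 counts each, but the list members' share of 1.73% only 2.96 to 4.35. The first, narrower criterion left 2 genes (ratio 1.63) and was widened after that was seen. The shares were not uniform, with Stra8 at 20.44% and Nr2f2 at 0.67%, and a single share of RA material could not bring both. Added RA material could also lower a gene by no more than its own share of the RNA. Otx2 and Dnmt3b stood lower in NS libraries 2 and 3 than in library 1 by more than that, at the CPM given with the RA results. RA material thus cannot be the whole difference between these NS libraries. No biological explanation was tested, and retinoid activity in those NS cultures stays open.

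In Sorb300, 77 small nucleolar RNA genes had a median log2 fold change of 3.98 (60 rose, 0 fell). A rise in the counted RNA of the host genes is argued against. The 54 tested hosts had a median of -0.53 (SD 0.80, 2 rose, 21 fell). With a host taken once for each of its small nucleolar RNA genes, the ratio of the medians was -0.16. Counts per gene from a 3' kit do not separate reads of unspliced host RNA, which was not tested and stays open. A general gain of RNA without a poly(A) tail stays open. The 52 histone genes, whose RNA also lacks the tail, had a median of -0.93 (SD 1.51, 4 rose, 10 fell), below 0 by less than their spread. That spread is between genes and does not measure the error of the median. As a set these genes were lower in camera (unadjusted p = 0.00991), but not with an estimated correlation (unadjusted p = 0.474). The rule written beforehand counted any median below 0 against this explanation, and weighing it by the spread departed from that rule. The histone median was -0.40 without NS library 3 and -0.46 without Sorb300 library 1, and fewer cells in S phase could lower it. Yet G1 and S phase genes stood at medians of -0.27, 0.34 and 0.11 from the NS mean in Sorb300 libraries 1, 2 and 3. Within Sorb300, libraries 2 and 3 stood above library 1 by a median of 1.35 for histone genes and 1.54 for small nucleolar RNA genes, against 0.57 for G1 and S phase genes and -0.04 for all genes. A change in these RNAs in hyperosmotic culture is another candidate explanation, and a step of library preparation that favours short RNA is one that was not tested.

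Replicate-3 libraries stood apart from replicates 1 and 2, with 80 ribosomal protein genes higher by 0.51 on the log2 scale. Library depth is argued against, as replicate 3 had the lowest total in 6 and the highest in 5 of 12 groups. Gene length fits the difference: across 13373 genes, which are not independent replicates, the Spearman correlation was -0.31 with length and 0.14 with GC content, so a technical difference in RNA or library preparation may contribute. No biological explanation was tested.

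The 6 libraries of a comparison can be split in 10 ways, the real one included, too few for a share under 0.05. The real split called 161 genes in ND (highest other split 2), 3259 in RA (0), 10 in PFOA60 (0) and 2450 in RA against ND (0), each the only 1 of 10 to call as many. In Sorb300 it called 4102, and another split called 2009, which points to a structure of the Sorb300 libraries, where library 1 stood apart. In PFOA100 the real split called 0 and another split 7. The other comparisons of 2 groups called 0 in all 10 splits. Where the numbers pair, 4 of 10 splits part all 3 pairs; among these the highest other was 2 for ND and 0 for the rest. For the 4 higher doses the real count was 0, which all 100 drawn splits reach whatever the data (highest other 1), so the splits decide nothing there.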

How the results depend on the processing

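The likelihood ratio test, the fit without replicate-3 libraries, the fit without NS libraries 2 and 3 and the list and signature tests with a library left out were chosen after the data were seen. Counts given neither here nor with the results stayed within 1.5 times, and where no cause is named the cause was not tested.

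By setting, the counts that moved were as follows. With the replicate block, ND had 552, PFOA60 47 and Cort60 6, where the numbers did not pair. In the comparisons whose numbers pair, the block moved no other gene count by over 1.5 times and changed no other list call than those given with the results, while more list members were called in ND and PFOA60. In the other 6 the lowest pair correlation was -0.23 to 0.09. Without replicate-3 libraries, ND had 42 and PFOA60 0. Without NS libraries 2 and 3, with fewer samples, ND had 1, RA 1410, Sorb300 1513 and PFOA60 0. The likelihood ratio test gave ND 359, BP1 4, BP4 3, Cort60 16, PFOA60 104, PFOA100 2 and the 4 higher doses 3. DESeq2 gave ND 338, BP1 1, BP4 2, Cort60 10 and PFOA60 80. With only the compared groups in the fit, Sorb300 had 2284, PFOA60 1 and RA against ND 4072. PFOA60 had 4 with no filter and 6 at a mean of 10 CPM. Of 464 list tests camera passed 122, 24 with an estimated correlation, 73 by fry and 131 with the block. With RLE factors the share of calls that were higher went from 42.7 to 51.8% in RA.

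Leaving out 1 library, counts ran from 32 (without NS 2) to 312 (without NS 1) in ND, 1886 (without NS 3) to 2867 in RA (2037 without RA 1), 2949 to 4922 in Sorb300, 1509 (without RA 1) to 2005 in RA against ND (1613 without ND 3), 0 to 40 (without NS 1) in PFOA60 and 0 to 37 (without PFOA100 1) in PFOA100. Without NS 1 the counts rose from 0 to 5 in BP1, 6 in BP4, 6 in Cort10, 17 in Cort60, 1 in DEP5 and 4 in DEP10, each the highest of a range from 0. The 4 dose comparisons and the test of higher doses stayed at 0. Of 122 list calls by camera 58 held on every such test, and 19 of 24 with an estimated correlation. The 2 signature calls between the PFOA doses became 0 without PFOA100 1 and 1 without PFOA100 3 or PFOA60 1, and the calls in all became 3 without BP4 3, Cort10 1, Cort60 3 or DEP5 3.

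Of 327 pairs of a named gene and a comparison, 210 were called, and 41 of these moved by over 1.5 times on leaving out 1 library. Their 3043 alternative values held the call in 2717 cases, lost it in 326 (181 on leaving out 1 library, 58 without NS libraries 2 and 3) and reversed in 0. Among uncalled genes 28 values changed sign, 23 of them without NS libraries 2 and 3. The latter log2 values were, for Otx2, -0.47 (BP1), -0.44 (BP4), -0.25 (Cort10), -0.21 (Cort60), -0.50 (DEP5) and -0.48 (DEP10); for Epcam -0.048 (ND), -0.37 (DEP10) and -0.24 (PFOA60); for Cyp1b1 -0.62 (BP1) and -0.36 (BP4); for Utf1 -0.24 (BP4) and -0.32 (DEP5); for Dppa2 0.024 (Cort10) and 0.048 (PFOA100). The others were Nanog 0.031, Cdh2 0.043 and Nqo1 0.051 in BP1, Pdk4 1.66 in Cort10, Tcfcp2l1 0.12 in Cort60, Tbx3 0.19 in DEP5, Dppa3 0.50 in DEP10 and Dnmt3b -0.35 in PFOA60. Cyp1b1 went to -0.33 in BP1 without replicate-3 libraries and, in BP4 against BP1, to -0.15 without BP1 1 and -1.05 without BP4 2 (highest 1.07, without BP1 3). Epcam in DEP10 went to -0.015 without NS 2 (highest 0.66, without NS 1), and Dnmt3b in Sorb300 to 0.32 without NS 1 (lowest -1.06, without NS 2).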
